A study of Mus musculus with 18 samples.

How the data were processed

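RNA sequencing of isolated mouse heart cells was analysed from the deposited tables. Per the labels, 18 libraries came from 6 mice aged 16 months, 3 Bag3-P209L Tg+ and 3 Bag3-WT. Cardiomyocytes gave 12 libraries, 2 per mouse (rep1 and rep2), and fibroblasts 6, 1 per mouse. Per the labels' protocols, total RNA was extracted from hearts, messenger RNA was captured on oligo(dT) beads, fragmented and made into Illumina libraries. The labels state that cardiomyocyte samples had an additional round of sequencing, without saying whether rep1 and rep2 are those rounds. The animal codes hold the letter F (Tg mouse 1, Tg mouse 3, WT mouse 1) or M (Tg mouse 2, WT mouse 2, WT mouse 3). The letter was thus unevenly spread over the genotypes, and the main genotype fits did not include it. Whether the transgene is of mouse or human sequence, and whether its reads were counted as Bag3, is not given in the sources used here.

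The first deposited table held estimated counts (expected counts) per gene, of which 44.7% of the values were not whole numbers. The submitters' processing notes name kallisto 0.44.0, DESeq2 1.18.1, R 3.4.4 and the build GRCm38.p6, and give no role or order for them. The annotation, the step from transcripts to genes and any filter are not given in the sources used here. The second deposited table held a normalized signal, the estimated count divided by a factor that differed between genes and libraries, which was read from the values. Relative to the median of a library these factors ran from 0.366 (lowest 5th percentile) to 1.47 (highest 95th percentile). All tests used the first table. Both tables listed the same 19094 protein-coding genes, and 0 columns could not be mapped to a sample. Gene positions came from GENCODE M21 on GRCm38, which held 17584 of these symbols (92.1%).

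The expected counts of rep1 and rep2 of a mouse were summed and rounded to whole numbers, which gave 12 columns, 1 per mouse and cell type. The mouse was the unit of replication. Repeats were checked by the Pearson correlation of log2 CPM (prior count 1) and by chi-squared per degree of freedom over genes with at least 10 summed counts. The correlation of repeats within a mouse in the mixed model was 0.743. The repeat number pairs no mice across genotypes. Deviations from the group means of cardiomyocyte libraries with the same repeat number in the other genotype correlated at a mean of 0.0109 (lowest −0.378, highest 0.357), so the number was not used as a replicate block in the main fits.

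Genotype was tested in each cell type alone (3 against 3 mice). Cell type was tested within mice (6 mice, mouse as block), and the difference of the genotype effect between cell types as an interaction in the same layout. Tests used edgeR 4.0.16 in R 4.3.3 with filterByExpr, TMM scaling, robust glmQLFit and glmQLFTest, two-sided, and Benjamini-Hochberg adjusted p < 0.05. Genes tested were 12439 in cardiomyocytes, 13571 in fibroblasts and 13891 in the paired layouts. The spread of genes between mice (common biological coefficient of variation) was 0.495, 0.284, 0.381 for the interaction and 0.361 for cell type. CPM values in the genotype comparisons are TMM-scaled within a cell type, and those of the paired comparisons over all 12 columns. The mitochondrial genes stayed in the library sizes except where stated. Values given per nuclear counts leave the 13 mitochondrial genes out.

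Gene lists (34, of which 31 had at least 5 tested genes) and the rule for naming genes were written before the data were examined, as were the comparisons, tests and most alternatives. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. They were tested again with a correlation estimated from the data and with fry. Some genes, such as Ttn and Ryr2, stand in more than 1 list, so the list results are not independent. camera asks whether a list moves against all other genes, and fry whether it moves on balance in 1 direction, whatever other genes do. A count called "adjusted over the list alone" used Benjamini-Hochberg within a list.

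Bag3 was always named. Where a direction had genes past the threshold, up to 8 with the largest change were to be named (5 for the interaction), with a mean of at least 5 CPM in the higher group and no overlap between genotypes, leaving out predicted genes and the sex-linked list. Where fewer than 3 passed, the 3 with the lowest p were named as not passing. Up to 4 members with the lowest p were named from each list with passing genes, 2 for lists of other cell types and 3 for each list called by genotype. Not every item that this rule names is reported here. Dhx35, Stard9, Wif1, Ttn, Nanp, Bsx, Cd5l, Marco, Nlrp1b and Saa3 are named as calls of alternative tests. The airway, alveolar, thyroid, testis and skin and limb genes, Usp9y and Uba1y were chosen after their values or those of related genes were seen. Their lists were written to a file before the tests that use them were run, the ciliated and basal list before its own values were seen.

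The floor for a group without counts was 3 counts, and floors and counting intervals cover counting error only, not variation between mice. The 3-count floor lay between 0.190 and 1.33 CPM of nuclear counts. Mitochondrial shares were compared by exact permutation of the mice (genotype) and by exact sign flips (cell type), both two-sided. With 3 against 3 mice the exact p cannot fall below 0.1.

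The scripts were tested on simulated data drawn from the fitted means, gene-wise spread and library sizes of each comparison, with 200 changed genes planted. The first planting had folds up to 4. edgeR found 0 of 66 4-fold changes in cardiomyocytes, 47 of 66 in fibroblasts, 8 of 66 in the interaction and 50 of 66 between cell types. Since it made no call in cardiomyocytes, a planting up to 16-fold was added after that was seen. There edgeR found 44 of 50 16-fold, 12 of 50 4-fold and 1 of 50 2-fold changes in cardiomyocytes, with 7 false among 64 calls. DESeq2 made 23 false calls among 57 in cardiomyocytes and 37 among 117 in fibroblasts in the first planting. A planted list of 20 genes with a 2-fold change had adjusted p = 5.73e-10 (preset), 0.0614 (estimated correlation) and 1.71e-05 (fry) in cardiomyocytes. In fibroblasts these were 2.81e-24, 0.0109 and 3.13e-04. None of the 31 fixed lists was called in unchanged simulated data by any of the 3 methods. Each gene was drawn independently there, so the simulated lists had no inter-gene correlation. In the real cardiomyocyte columns the estimated correlation was 0.746 for the cardiomyocyte markers and 0.940 for the mitochondrially encoded genes. The self-test therefore does not show how often camera with the preset of 0.01 makes false calls in these data.

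Alternatives were RLE size factors, library size only, DESeq2 1.42.0, limma voom, 1 CPM in 3 columns or 1 count in any column as filter, adjusted p < 0.1, and a 1.5-fold minimum. Further ones were leaving out each mouse in turn, the letter as covariate, the sex-linked list left out, a joint fit of 12 columns, a fit without the robust option, and markers of the other cell type as covariate. Repeats were also entered unsummed with the replicate number as a block, once with the mouse as random effect (limma with statmod 1.5.0) and once with libraries counted as independent, or restricted to rep1 or rep2. For cell type the mouse block was dropped. Added once the values were known were fits without mitochondrial genes, with the deposited factors as offsets, and without Tg mouse 3 and WT mouse 3. No library was left out of the main fits.

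Chance was gauged by refitting all 10 splits of the 6 mice into 3 against 3 and all 32 exchanges of cell types within mice. Copies of genes were sought by shared stretches of 31 bases between single-exon and multi-exon genes, where at least 10% of the stretches had to be shared. A copy was high in cardiomyocyte and near 0 in fibroblast libraries at over 10 and under 1 CPM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for this step and the figures. Xist was named in the sex-linked list and is not analysed here, since the table lists protein-coding genes only.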

Results

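The series compared heart cells of mice carrying a Bag3-P209L transgene (Tg+) with those of Bag3-WT mice, all aged 16 months. BAG3 is a co-chaperone that joins HSP70 to small heat shock proteins and sends damaged sarcomere proteins to autophagy. P209L exchanges a proline of BAG3 for a leucine. Cardiomyocytes and cardiac fibroblasts came from 3 Tg+ and 3 Bag3-WT mice. Each mouse gave 1 fibroblast library and 2 cardiomyocyte libraries, called rep1 and rep2 in the labels, whose counts were summed. This left 12 columns from 18 libraries, with the mouse as the unit of replication. The deposited table held expected counts (estimated read counts per gene, partly not whole numbers) of 19094 protein-coding genes.

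Most cardiomyocyte counts belonged to the 13 protein genes of the mitochondrial genome, which encode parts of the respiratory chain. Their share was 67.1 ± 13.3% (mean ± SD, n = 3) in Tg+ and 81.2 ± 7.21% in Bag3-WT cardiomyocyte libraries (exact permutation p = 0.3, two-sided). In fibroblast libraries it was 30.8 ± 12.3% and 43.6 ± 26.7% (exact permutation p = 0.6, two-sided), with WT mouse 1 highest at 74.2%. The gene of cytochrome c oxidase subunit 1, mt-Co1, had the most counts in every library. Within mice the share was higher in cardiomyocyte than in fibroblast libraries by 36.9 ± 20.7 percentage points (n = 6, exact sign-flip p = 0.0312, two-sided). Columns held 10.9 M to 17.2 M counts (M, 1e6) in cardiomyocytes and 17.3 M to 61.3 M in fibroblasts. Nuclear genes were left with 2.26 M to 7.79 M and 11.3 M to 15.8 M of them, so that 3 counts stood for 0.190 to 1.33 counts per 1e6 (CPM) of nuclear counts.

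The rep1 libraries held 1.22 M to 5.64 M counts and the rep2 libraries 9.29 M to 13.9 M. Log counts of rep1 and rep2 of the same mouse correlated at r = 0.936 to 0.978 (6 pairs), against 0.703 to 0.948 between different mice (60 pairs). Scatter between repeats of a mouse, as chi-squared per degree of freedom, was 1.61 to 5.01, where 1 is counting error alone. Without the mitochondrial genes it was 1.51 to 1.69, and 4.82 to 88.7 between different mice.

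Bag3 (ENSMUSG00000030847.8, chromosome 7, 128523616 to 128546981, plus strand), the targeted gene, was checked before any comparison and was counted in all 18 libraries. Cardiomyocytes held 45.2 ± 10.4 CPM in Tg+ and 54.4 ± 36.5 CPM in Bag3-WT mice (log2 fold change, log2FC, −0.27, standard error, SE, 0.48, edgeR adjusted p = 1.00, n = 3 each). Fibroblasts held 214 ± 89.2 and 195 ± 56.6 CPM (log2FC 0.13, SE 0.36, adjusted p = 0.939). Counts per mouse were 1568, 658 and 561 in Tg+ against 880, 410 and 403 in Bag3-WT cardiomyocytes. In fibroblasts they were 5739, 7000 and 2566 against 3636, 6307 and 4001. The sign of Bag3 hung on single mice. Without WT mouse 1, Bag3 by genotype in cardiomyocytes was 0.447, and Bag3 by genotype in fibroblasts was −0.0617. Without Tg mouse 2, Bag3 by genotype in fibroblasts was −0.201. The labels do not state the species of the transgene or whether its reads count as Bag3, so these values neither show nor exclude transgene expression. Bag3 was lower in cardiomyocyte than in fibroblast libraries of the same mice (log2FC −1.20, SE 0.34, adjusted p = 0.0152, n = 6).

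**Figure D1:**
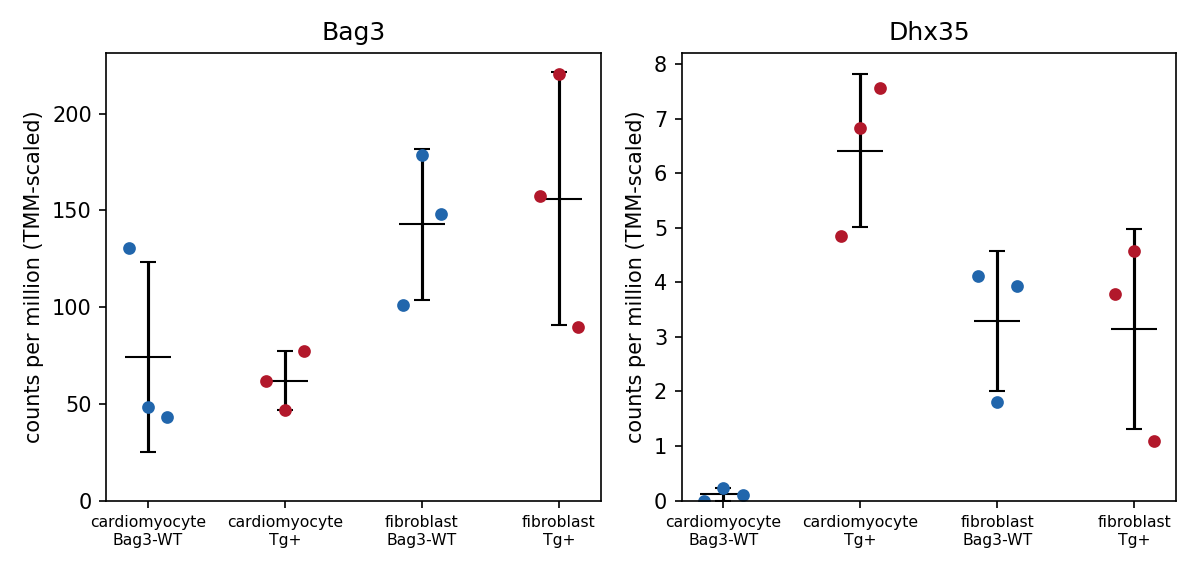
Bag3 and Dhx35 in CPM (vertical axis, TMM-scaled over all 12 columns) by cell type and genotype (horizontal axis). Each point is a mouse (blue Bag3-WT, red Tg+), the cross bar is the mean and the whiskers are the SD, n = 3 mice.

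The Y chromosome genes Ddx3y, Eif2s3y, Kdm5d and Uty followed the letter F or M in the animal codes of all 6 fibroblast libraries. Libraries with letter M held 908 to 1300 counts of the RNA helicase gene Ddx3y and 367 to 403 of the translation factor gene Eif2s3y. Those with letter F held 0 of each. In fibroblasts the letter thus went with sex as read from these genes. Since the letter was unevenly spread over the genotypes, sex and genotype are partly confounded in the main fits. The histone demethylase gene Kdm5d had 53 to 63 counts with letter M and 5 to 9 with letter F. The deubiquitinase gene Usp9y (at most 4 counts) and the ubiquitin activation gene Uba1y (at most 6), picked after their values were seen, stayed near 0 in fibroblasts with either letter. Cardiomyocyte libraries with letter M held 101 to 274 Ddx3y counts. Tg mouse 3, with letter F, was an exception, with 62 Ddx3y, 172 Eif2s3y, 96 Usp9y and 0 Uty counts in its cardiomyocyte libraries. With letter M, cardiomyocytes held 90 Usp9y counts in WT mouse 3, 26 in Tg mouse 2 and 4 in WT mouse 2. Eif2s3y also had 24 counts in cardiomyocytes of Tg mouse 1 and 19 in those of WT mouse 1, both with letter F. Uba1y did not follow the letter in cardiomyocytes, with 25, 71 and 109 counts in Tg mouse 1, WT mouse 1 and Tg mouse 3 against 53, 11 and 126 in Tg mouse 2, WT mouse 2 and WT mouse 3.

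The first comparison asked how the cardiomyocyte libraries differed from the fibroblast libraries of the same mice. Heart muscle and respiratory chain genes were higher in cardiomyocyte libraries, while macrophage, cytokine, antigen presentation and stress response genes were lower. All 13 cardiomyocyte markers were higher, by a median log2FC of 1.92 (camera adjusted p = 1.88e-07, adjusted p = 0.241 with an estimated correlation). The Z-disc crosslinker gene Actn2 was higher by 1.95 (SE 0.25, adjusted p = 1.35e-04), the ventricular myosin light chain gene Myl2 by 2.22 (SE 0.29, adjusted p = 1.56e-04). Myl3, another myosin light chain gene, was higher by 1.92 (SE 0.26) and Ryr2, the calcium release channel of the sarcoplasmic reticulum, by 1.97 (SE 0.27). Fibroblast libraries still held 62.7 CPM of Myl2 in Tg+ and 88.5 CPM in Bag3-WT mice, against 272 and 417 CPM in cardiomyocytes. Of 22 sarcomere and Z-disc genes, 18 were higher and 0 lower (median 1.56, camera adjusted p = 9.45e-08, adjusted p = 0.240 with an estimated correlation). Among them were the calcineurin-binding Z-disc gene Myoz2 (2.35, SE 0.25), the titin-binding LIM gene Fhl2 (1.98, SE 0.22) and filamin C, Flnc (2.54, SE 0.34), a client of BAG3. Calcium handling and ion channel genes were higher in 11 and lower in 2 of 20 (median 1.16, camera adjusted p = 2.99e-04, adjusted p = 0.240 with an estimated correlation). The calcium store genes Casq2 (2.48, SE 0.21), Hrc (2.23, SE 0.24) and Trdn (2.50, SE 0.33) rose most clearly. Cardiac stress and fetal genes were higher in 7 and lower in 1 of 9 (median 1.87, camera adjusted p = 0.00504, adjusted p = 0.240 with an estimated correlation). The natriuretic peptide gene Nppb was higher by 3.87 (SE 0.39), the muscle ankyrin repeat gene Ankrd1 by 2.18 (SE 0.24) and the actin-binding intercalated disc gene Xirp2 by 2.83 (SE 0.41), while the calcineurin inhibitor gene Rcan1 fell by 2.93 (SE 0.23).

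Energy metabolism genes moved with the muscle genes. Nuclear genes of oxidative phosphorylation were higher in 62 of 68, lower in 0 (median 0.99, camera adjusted p = 2.88e-16, adjusted p = 0.240 with an estimated correlation). The complex I genes Ndufb9 (1.81, SE 0.19) and Ndufv2 (1.71, SE 0.19) were among them. All 13 mitochondrially encoded genes were higher (median 2.08, camera adjusted p = 8.87e-06, adjusted p = 0.323 with an estimated correlation), with mt-Nd3 of complex I at 3.49 (SE 0.55) and mt-Atp6 of ATP synthase at 2.20 (SE 0.50). Fatty acid oxidation genes were higher in 17 of 23 (median 1.09, camera adjusted p = 1.96e-07, adjusted p = 0.240 with an estimated correlation), among them the thiolase gene Acaa2 (1.28, SE 0.17) and the fatty acid carrier gene Fabp3 (1.75, SE 0.27). Genes of mitochondrial dynamics, mitophagy and biogenesis were higher in 10 of 19 (median 0.57, camera adjusted p = 0.00452, adjusted p = 0.240 with an estimated correlation), including the fusion gene Mfn2 (1.10, SE 0.17) and the mitophagy receptor gene Bnip3 (1.05, SE 0.21). Glycolysis genes split, 6 higher and 5 lower of 19 (median 0.15, camera adjusted p = 0.364). The heart lactate dehydrogenase gene Ldhb (1.71, SE 0.18), the muscle enolase gene Eno3 (1.71, SE 0.20) and the insulin-regulated glucose transporter gene Slc2a4 (2.24, SE 0.24) were higher, the hexokinase gene Hk2 lower (−3.14, SE 0.34).

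Fibroblast markers did not separate the preparations, with 2 higher and 1 lower of 13 in cardiomyocyte libraries (median −0.29, mean 0.06, camera upward, adjusted p = 0.880). The collagen genes Col1a1 (2.52, SE 0.57, adjusted p = 0.00505) and Col1a2 (1.38, SE 0.48, adjusted p = 0.0373) were higher, and Col1a2 moved to 0.92 without WT mouse 1. The epicardial transcription factor gene Tcf21 was lower (−0.98, SE 0.31, adjusted p = 0.0263). Extracellular matrix and fibrosis genes were higher in 4 and lower in 6 of 24 (median −0.43, camera adjusted p = 0.671). The fibronectin gene Fn1 rose by 1.88 (SE 0.36), while the growth factor gene Tgfb1 (−2.24, SE 0.19), the osteopontin gene Spp1 (−2.41, SE 0.26) and the protease inhibitor gene Timp1 (−2.27, SE 0.44) fell. Smooth muscle and pericyte markers were higher in 9 of 10 (median 1.40, camera adjusted p = 3.88e-05, adjusted p = 0.240 with an estimated correlation), among them the actin-binding genes Tagln (3.34, SE 0.34) and Cnn1 (3.46, SE 0.36). Myofibroblast activation genes were higher in 6 and lower in 1 of 9 (median 2.25, camera adjusted p = 0.0161, adjusted p = 0.240 with an estimated correlation). The smooth muscle actin gene Acta2 was at 4.14 (SE 0.57, 51.4 to 923 CPM over cardiomyocyte columns) and the TGF-beta binding gene Ltbp2 at 2.94 (SE 0.69). Tagln and Cnn1 belong to both the smooth muscle and the myofibroblast list, so these are not separate results. Mesothelial markers were higher in 6 and lower in 1 of 7 (median 2.71, camera adjusted p = 0.00510, adjusted p = 0.294 with an estimated correlation), such as the membrane gene Lrrn4 (3.13, SE 0.29) and the uroplakin gene Upk3b (2.64, SE 0.30). Endothelial markers were lower in 2 of 12 (median −0.02, camera adjusted p = 0.856), namely the tight junction gene Cldn5 (−2.39, SE 0.31) and the receptor gene Tie1 (−0.81, SE 0.22).

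Immune and stress genes were lower in cardiomyocyte libraries. Of 17 inflammatory cytokine genes, 15 were lower (median −5.60, camera adjusted p = 1.37e-10, adjusted p = 0.240 with an estimated correlation). The chemokine genes Ccl4 (−8.16, SE 0.38, 286-fold), Ccl2 (−6.35, SE 0.31) and Cxcl2 (−8.32, SE 0.42) and the tumour necrosis factor gene Tnf (−7.56, SE 0.39) were among them. All 13 macrophage and myeloid markers were lower (median −2.37, camera adjusted p = 2.49e-08, adjusted p = 0.240 with an estimated correlation), led by the lipopolysaccharide co-receptor gene Cd14 (−4.72, SE 0.24, 26.4-fold) and the lysosomal gene Cd68 (−3.46, SE 0.26). All 7 MHC class II genes were lower (median −2.65, camera adjusted p = 4.83e-05, adjusted p = 0.240 with an estimated correlation), for instance the beta chain gene H2-Ab1 (−2.77, SE 0.20) and the invariant chain gene Cd74 (−2.79, SE 0.25). Interferon response genes were lower in 17 and higher in 1 of 19 (median −2.06, camera adjusted p = 1.29e-06, adjusted p = 0.255 with an estimated correlation), with the chemokine gene Cxcl10 at −7.64 (SE 0.31) and the antiviral gene Rsad2 at −5.12 (SE 0.33). Immediate early genes were lower in 15 of 17 (median −2.04, camera adjusted p = 9.11e-07, adjusted p = 0.240 with an estimated correlation), such as Atf3 (−5.09, SE 0.41) and the AP-1 subunit gene Fosb (−4.61, SE 0.45). Lymphocyte markers were lower in 6 of 12 (median −0.89, camera adjusted p = 0.0628), including the cytokine receptor gene Il7r (−2.23, SE 0.27) and the B cell receptor gene Cd79a (−2.29, SE 0.39). All 5 erythroid markers were lower (median −1.61, camera adjusted p = 0.00960, adjusted p = 0.342 with an estimated correlation), with the globin gene Hba-a2 at −1.71 (SE 0.29).

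Genes of the unfolded protein and integrated stress response were lower in 12 of 17 (median −1.14, camera adjusted p = 5.92e-04, adjusted p = 0.240 with an estimated correlation). The stress cytokine gene Gdf15 was lower by 7.10 (SE 0.32) and the death-linked transcription factor gene Ddit3 by 1.85 (SE 0.20). Oxidative stress defence genes were lower in 8 and higher in 1 of 15 (median −1.37, camera adjusted p = 0.00510, adjusted p = 0.241 with an estimated correlation), with the heme oxygenase gene Hmox1 at −6.64 (SE 0.30) and the sulfiredoxin gene Srxn1 at −5.46 (SE 0.26). Genes of p53 and apoptosis were lower in 12 and higher in 3 of 17 (median −1.25, camera adjusted p = 0.00807, adjusted p = 0.240 with an estimated correlation), including the cell cycle inhibitor gene Cdkn1a (−2.83, SE 0.28) and the p53 ligase gene Mdm2 (−2.42, SE 0.22). Cell cycle genes were higher in 11 and lower in 2 of 24 (median 0.83, camera adjusted p = 0.00196, adjusted p = 0.240 with an estimated correlation). The topoisomerase gene Top2a (2.05, SE 0.26) and the centromere gene Cenpf (2.45, SE 0.27) rose and the replication clamp gene Pcna fell (−2.18, SE 0.19). Proteasome genes were higher in 10 and lower in 1 of 31 (median 0.43, camera adjusted p = 0.00315, adjusted p = 0.414 with an estimated correlation).

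The heat shock and BAG3 chaperone network split evenly, with 8 higher and 8 lower of 23 (median −0.06, mean 0.11, camera upward, adjusted p = 0.552). The small heat shock protein genes Cryab (1.60, SE 0.21), Hspb2 (2.62, SE 0.37) and Hspb7 (1.85, SE 0.26) were higher in cardiomyocyte libraries and the HSP70 partner gene Dnajb6 lower (−1.62, SE 0.17). Autophagy and lysosome genes were higher in 3 and lower in 9 of 23 (median −0.14, camera adjusted p = 0.257). The autophagy receptor genes Sqstm1 (−3.57, SE 0.24, 11.9-fold) and Optn (−2.01, SE 0.20) and the lysosomal protease gene Ctsb (−2.20, SE 0.22) fell. Circadian clock genes were higher in 1 and lower in 6 of 13 (median −0.62, camera adjusted p = 0.0656), with the repressor gene Cry1 at −2.06 (SE 0.25). Cytosolic ribosomal protein genes were higher in 3 and lower in 1 of 38 (median 0.03, camera adjusted p = 0.552).

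**Figure D2:**
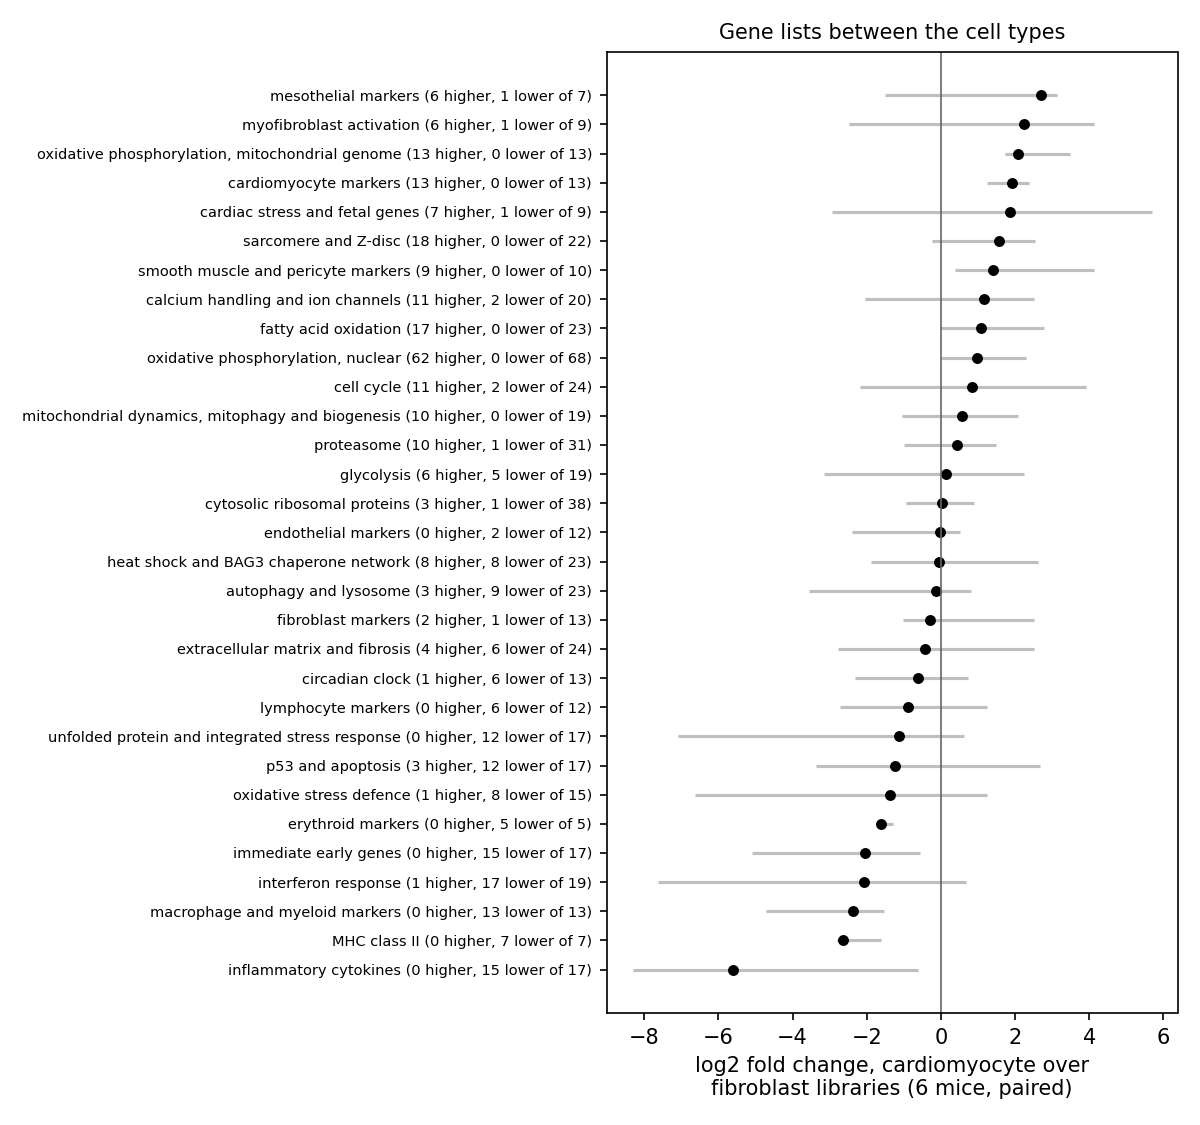
Gene lists between the cell types. The horizontal axis is the log2 fold change of cardiomyocyte over fibroblast libraries paired within 6 mice, each line of the vertical axis is a list with its numbers of higher and lower genes, points are list medians and grey lines run from the lowest to the highest member.

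Of 13891 genes tested, 2734 were higher and 3456 lower in cardiomyocyte libraries (edgeR quasi-likelihood, adjusted p < 0.05), 6190 in all. DESeq2 called 7094 and limma voom 6879. Scaling by library size only shifted the median of all genes by −0.95 and turned the balance to 457 higher and 6616 lower, so only differences relative to other genes are read here. The estimated correlation left no list past adjusted p < 0.05, while fry, which asks whether genes move on balance in 1 direction and makes no contrast with other genes, gave adjusted p = 0.00174 for the cardiomyocyte markers and 1.30e-04 for the macrophage markers. The cell types were isolated as separate preparations, and cell content, isolation and cell-intrinsic levels cannot be told apart.

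The next comparison asked which genes differed between Tg+ and Bag3-WT cardiomyocytes. No gene passed the test, and the heart muscle genes lay lower in Tg+ mice as a group. The number of called lists cannot set the genotypes apart. Of 10 splits of the 6 mice, 2, the real one included, reached the real 15 lists, and 10 splits are too few to judge chance. All 13 cardiomyocyte markers had negative values (median log2FC −0.63, camera adjusted p = 7.02e-10, adjusted p = 0.567 with an estimated correlation), and 1 of them passed when adjusted over the list alone, against 0 of 12439 over all genes. Titin, Ttn, the elastic filament of the sarcomere, stood at 16.5 ± 3.93 CPM in Tg+ and 38.6 ± 3.92 CPM in Bag3-WT mice (log2FC −1.23, SE 0.30, edgeR adjusted p = 1.00, n = 3 each). Ryr2 was at −1.06 (SE 0.33, 10.5 against 21.8 CPM) and the myosin-binding protein gene Mybpc3 at −0.94 (SE 0.32, 50.2 against 96.4 CPM). Sarcomere and Z-disc genes were negative in 17 of 22 (median −0.60, camera adjusted p = 2.93e-08, adjusted p = 0.567 with an estimated correlation), such as the M-band gene Myom1 (−0.97, SE 0.32, 24.4 against 47.8 CPM). Calcium handling and ion channel genes were negative in 16 of 19 (median −0.46, camera adjusted p = 3.62e-06, adjusted p = 0.567 with an estimated correlation), among them the junctional membrane gene Jph2 (−0.74, SE 0.30) and the potassium channel partner gene Kcnip2 (−0.99, SE 0.44). Cardiac stress and fetal genes were negative in 8 of 9 (median −0.34, camera adjusted p = 0.00163, adjusted p = 0.567 with an estimated correlation), and 2 passed adjusted over the list alone, against 0 over all genes. Xirp2 was at −1.47 (SE 0.42, 13.9 against 38.4 CPM), Ankrd1 at −1.05 (SE 0.32, 22.3 ± 6.61 against 46.1 ± 4.67 CPM) and the atrial natriuretic peptide gene Nppa at −0.91 (SE 0.80).

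Respiratory chain genes also lay lower. All 13 mitochondrially encoded genes were negative (median −1.02, camera adjusted p = 5.40e-12, adjusted p = 0.567 with an estimated correlation), including the complex I gene mt-Nd4l (−1.18, SE 0.56) and the ATP synthase gene mt-Atp8 (−1.20, SE 0.58). Their estimated correlation was 0.940, so they amount to little more than 1 measure per mouse. Their share of counts gave an exact permutation p = 0.3 (two-sided), and list scores overlapped (Tg mouse 3 at 14.9, WT mouse 3 at 14.7). Nuclear genes of oxidative phosphorylation were negative in 64 of 68 (median −0.27, camera adjusted p = 3.11e-08, adjusted p = 0.699 with an estimated correlation), with the complex III gene Uqcr10 at −0.66 (SE 0.29) and the complex I gene Ndufb5 at −0.60 (SE 0.27). Fatty acid oxidation genes were negative in 20 of 23 (median −0.22, camera adjusted p = 0.00230, adjusted p = 0.699 with an estimated correlation). Fabp3 was at −0.84 (SE 0.40, 70.8 against 127 CPM), the acyl-CoA dehydrogenase gene Acads at −0.61 (SE 0.30) and the lipid-sensing receptor gene Ppara at −1.39 (SE 0.76). Tg mouse 1 carried part of these differences. Without it the cardiomyocyte markers stood at −0.383, the sarcomere list at −0.319 and the mitochondrially encoded genes at −0.611 relative to all genes, each still called. The nuclear oxidative phosphorylation list (−0.179), the fatty acid list (−0.106) and the stress and fetal list (−0.337) lost their calls without this mouse, and the fatty acid list also lost it without WT mouse 2 (−0.260) and with library size only (−0.284).

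Immune lists were lower in Tg+ cardiomyocytes. Interferon response genes were negative in 17 of 18 (median −0.62, camera adjusted p = 3.94e-06, adjusted p = 0.601 with an estimated correlation), with the interferon regulator gene Irf7 at −0.93 (SE 0.40) and the ubiquitin-like gene Isg15 at −0.89 (SE 0.52). Their call was kept without any 1 mouse, with values from −0.352 (without WT mouse 2) to −0.720 (without WT mouse 1). All 13 macrophage markers were negative (median −0.41, camera adjusted p = 3.28e-04, adjusted p = 0.699 with an estimated correlation), including the integrin gene Itgam (−0.64, SE 0.44), the complement gene C1qb (−0.51, SE 0.44) and the scavenger receptor gene Cd163 (−0.44, SE 0.43). The macrophage list was no longer called without Tg mouse 3 (−0.0325) or with the letter as covariate (−0.254). Lymphocyte markers were negative in 7 of 10 (median −0.49, camera adjusted p = 0.00334, adjusted p = 0.699 with an estimated correlation), such as the T cell co-receptor gene Cd4 (−1.17, SE 0.79), the B cell receptor gene Cd79b (−0.64, SE 0.59) and Il7r (−0.64, SE 0.74). This list was not called without Tg mouse 3 (−0.0509) or WT mouse 2 (0.118). Inflammatory cytokines were negative in 10 of 16 (median −0.31, camera adjusted p = 0.0355, adjusted p = 0.763 with an estimated correlation), with Cxcl2 at −1.32 (SE 0.71), Ccl4 at −1.16 (SE 0.83) and the chemokine gene Ccl7 at −0.84 (SE 0.64). The cytokine list reversed to 0.117 without Tg mouse 3 and lost its call without WT mouse 1 (−0.277) or WT mouse 2 (−0.231) and with the letter as covariate (−0.277). All 7 MHC class II genes were negative (median −0.23, camera adjusted p = 0.0320, adjusted p = 0.763 with an estimated correlation), among them the regulator gene Ciita (−0.89, SE 0.90), and the peptide-loading genes H2-DMb1 (−0.45, SE 0.65) and H2-DMa (−0.31, SE 0.57). This list reversed to 0.223 without Tg mouse 3 and was not called without WT mouse 2 (0.0128) or WT mouse 3 (−0.273) or with the letter as covariate (−0.0372).

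Markers of the remaining cell types moved in both directions. All 12 endothelial markers were positive (median 0.32, camera adjusted p = 0.0234, adjusted p = 0.763 with an estimated correlation), including the sialomucin gene Emcn (0.64, SE 0.40), the vessel matrix gene Egfl7 (0.44, SE 0.31) and Cldn5 (0.37, SE 0.31). The endothelial list lost its call without Tg mouse 1 (0.0486), Tg mouse 2 (0.377) or WT mouse 3 (0.117), with library size only (0.538) and with the letter as covariate (0.285). Mesothelial markers were negative in 6 of 7 under TMM (median −0.40, camera adjusted p = 0.0201, adjusted p = 0.699 with an estimated correlation), with the mucin gene Muc16 at −0.49 (SE 0.81) and the mesothelin gene Msln at −0.58 (SE 1.05). The mesothelial gene Upk3b was at −0.40 (SE 1.05) under TMM but at 0.0864 relative to all genes when scaled by library size only, as was the median of this list. The mesothelial list reversed to 0.193 without Tg mouse 3 and was not called without WT mouse 1 (−0.0442) or WT mouse 2 (−0.262). Extracellular matrix and fibrosis genes were negative in 19 of 24 (median −0.34, camera adjusted p = 0.0281, adjusted p = 0.699 with an estimated correlation), such as Col1a1 (−1.30, SE 0.77, 857 against 2106 CPM), Col1a2 (352 against 706 CPM) and the collagen crosslinking gene Loxl2 (−0.74, SE 0.40). This list lost its call without Tg mouse 2 (−0.449), Tg mouse 3 (−0.303) or WT mouse 1 (−0.0612). Fibroblast markers were not called (median 0.09, mean −0.14, camera downward, adjusted p = 0.942). Smooth muscle markers (median 0.08, adjusted p = 0.606) and erythroid markers (median 0.03, mean −0.01, adjusted p = 0.237) were not called either.

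Genes nearest to the known work of BAG3 did not differ as groups. The heat shock and BAG3 chaperone network had 9 positive and 14 negative values of 23 (median −0.10, camera adjusted p = 0.520). Autophagy and lysosome genes had 11 positive and 12 negative values of 23 (median −0.00, camera adjusted p = 0.80). Proteasome genes were positive in 23 of 31 (median 0.25, camera adjusted p = 0.165), but lay at 0.82 against 0.84 for all genes with library size only, and the unfolded protein response had a median of 0.22 (camera adjusted p = 0.135). Myofibroblast activation genes had a median of 0.15 (camera adjusted p = 0.606), below all genes at 0.47 with library size only, and glycolysis genes of −0.28 (camera adjusted p = 0.213). Cell cycle genes (median 0.03, 0.63 and so below all genes with library size only, mean −0.20, camera adjusted p = 0.237) and p53 and apoptosis genes (median −0.10, mean 0.06, camera adjusted p = 0.606) were not called. The same held for mitochondrial dynamics (median −0.12, camera upward, adjusted p = 0.942) and immediate early genes (median 0.03, adjusted p = 0.606). Oxidative stress defence (median 0.02, camera downward, adjusted p = 0.972), the circadian clock (median 0.06, adjusted p = 0.350) and ribosomal proteins (median −0.03, adjusted p = 0.932) gave no call. The Schwann cell list had 1 tested gene and the adipocyte list 0, so neither was tested.

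Single genes with the smallest p values are given for orientation, among those with a mean of at least 5 CPM in the higher genotype and no overlap between genotypes, and none passed. Higher in Tg+ cardiomyocytes were the transmembrane gene Tmeff2 (log2FC 1.63, SE 0.49, 6.43 against 2.06 CPM), the phosphatase gene Ptpn2 (1.01, SE 0.38) and the actinin-binding gene Pdlim3 (0.92, SE 0.35, 19.8 against 10.5 CPM). Lower were the kinesin gene Stard9 (−2.50, SE 0.47, 1.43 against 8.18 CPM), the cardiac transcription factor gene Nkx2-5 (−1.83, SE 0.44, 1.98 ± 0.203 against 7.09 ± 3.09 CPM) and Ttn.

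**Figure D3:**
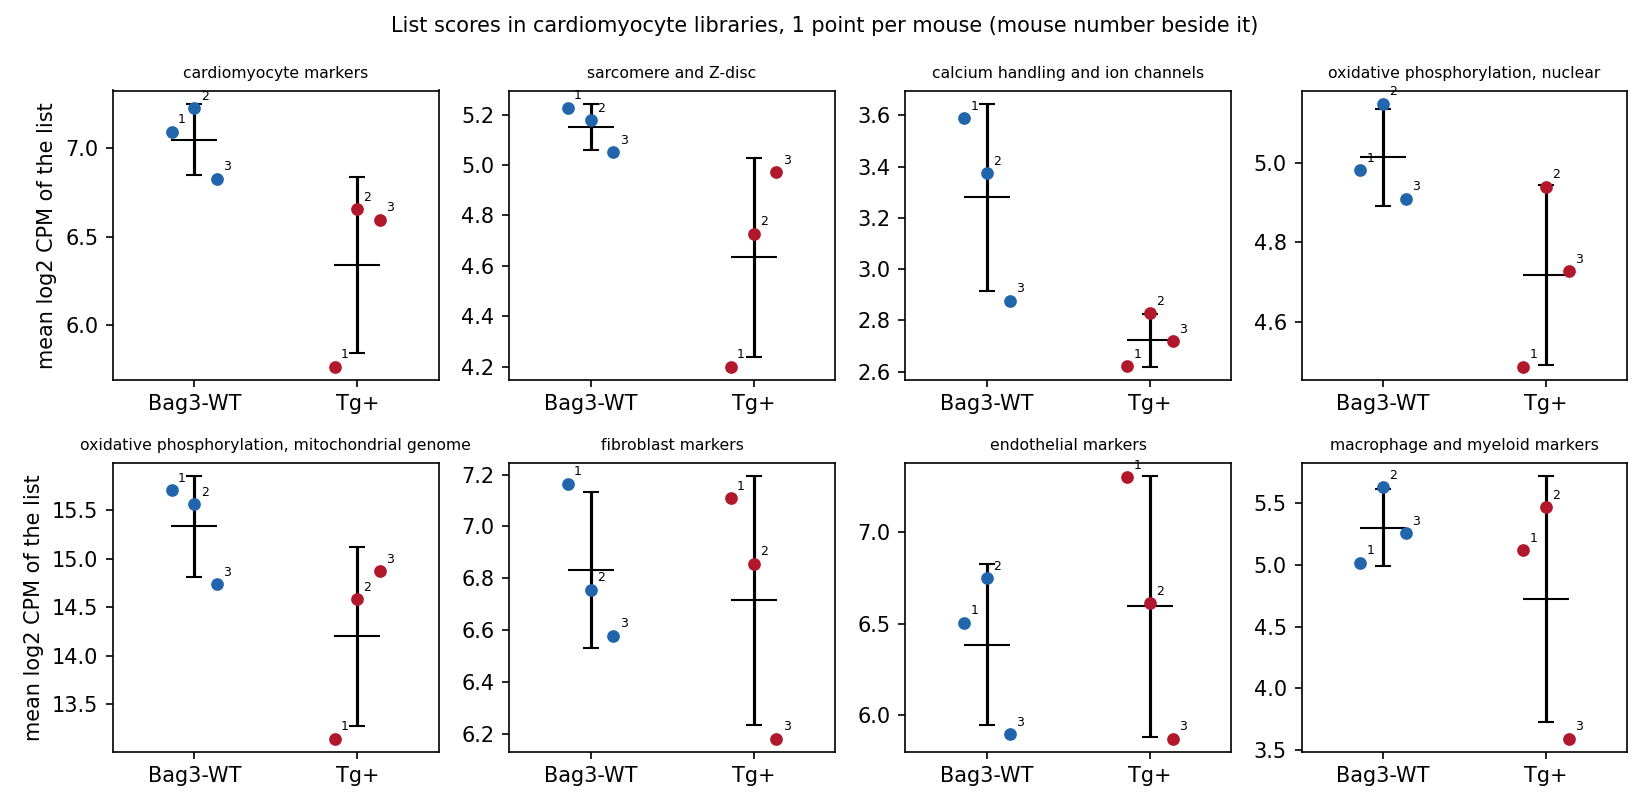
List scores in cardiomyocyte libraries, as the mean log2 CPM of the genes of each list (vertical axis) by genotype (horizontal axis). Each point is a mouse with its number beside it (blue Bag3-WT, red Tg+), the cross bar is the mean and the whiskers are the SD, n = 3 mice.

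Of 12439 genes, edgeR called 0 between genotypes in cardiomyocytes, with 89 under an unadjusted 0.05 (35 higher, 54 lower) against 622 expected by chance and a smallest adjusted p of 1.00. DESeq2 called 3 (Dhx35, Stard9 and Wif1) and limma voom 0. The values of the 3 Tg+ and 3 Bag3-WT mice did not overlap for 605 genes, 4.86%, where 10% arises by chance. In self-tests edgeR found 0 of 66 planted 4-fold changes in the first planting and 12 of 50 in the second, so many changes of this size are missed in these libraries. With library size only the median of all genes moved to 0.84, and those of the cardiomyocyte markers (0.11) and the sarcomere list (0.17) stayed below it. Camera called 15 of 31 lists, and with an estimated correlation or with fry (all adjusted p ≥ 0.355) 0 were called.

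The same question was put to the fibroblasts. No gene passed the test. Macrophage, cell cycle and MHC class II lists lay lower in Tg+ fibroblasts, and endothelial and fibroblast markers lay higher. The number of called lists did not set the genotypes apart, since 7 of 10 splits of the 6 mice, the real one included, reached the real 12 lists. All 13 macrophage markers were negative (median −0.74, camera adjusted p = 9.74e-08, adjusted p = 0.889 with an estimated correlation), and 0 passed adjusted over the list alone, as for all lists in fibroblasts. The lysozyme gene Lyz2 stood at −0.73 (SE 0.30, 1329 against 2198 CPM), the complement gene C1qa at −0.81 (SE 0.33, 607 against 1063 CPM) and Cd163 at −0.88 (SE 0.37, 177 against 325 CPM). Their value shrank to −0.408 without Tg mouse 3 and the call remained. All 7 MHC class II genes were negative (median −0.51, camera adjusted p = 0.00576, adjusted p = 0.889 with an estimated correlation), with H2-DMa at −0.68 (SE 0.30, 38.3 against 61.5 CPM), H2-DMb1 at −0.52 (SE 0.33) and Ciita at −0.56 (SE 0.40), and this list was not called without Tg mouse 3 (−0.165). Lymphocyte markers were negative in 10 of 12 (median −0.49, camera adjusted p = 0.0152, adjusted p = 0.889 with an estimated correlation), such as Cd4 (−0.72, SE 0.31), the T cell receptor gene Cd3e (−1.30, SE 0.61) and Il7r (−1.09, SE 0.51). The lymphocyte list lost its call without Tg mouse 2 (−0.394), Tg mouse 3 (−0.213) or WT mouse 1 (0.236).

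Cell cycle genes were negative in 22 of 24 (median −0.42, camera adjusted p = 1.02e-05, adjusted p = 0.889 with an estimated correlation). The cyclin gene Ccnb2 was at −0.72 (SE 0.23), Top2a at −0.77 (SE 0.26, 5.36 against 9.18 CPM) and the mitotic kinase gene Plk1 at −1.26 (SE 0.44). Their value shrank to −0.236 without WT mouse 3. Mesothelial markers were negative in 6 of 7 (median −1.50, camera adjusted p = 0.0152, adjusted p = 0.889 with an estimated correlation), with Msln at −1.98 (SE 0.83, 4.73 against 18.7 CPM), Upk3b at −1.81 (SE 0.81) and the keratin gene Krt19 at −1.54 (SE 0.71). That list was not called without Tg mouse 3 (−1.03), WT mouse 1 (−0.985) or WT mouse 2 (−1.50). All 12 endothelial markers were positive (median 0.45, camera adjusted p = 1.63e-04, adjusted p = 0.889 with an estimated correlation), including Egfl7 (0.50, SE 0.21), the VEGF receptor gene Kdr (0.66, SE 0.29, 250 against 158 CPM) and the angiopoietin receptor gene Tek (0.39, SE 0.17). All 13 fibroblast markers were positive (median 0.36, camera adjusted p = 0.0152, adjusted p = 0.889 with an estimated correlation), such as the collagen receptor gene Ddr2 (0.67, SE 0.39), the growth factor receptor gene Pdgfra (0.48, SE 0.47) and the decorin gene Dcn (0.47, SE 0.47). The fibroblast list was not called without Tg mouse 2 (0.298) or Tg mouse 3 (0.284), and without WT mouse 1 its median was 0.0328 and its tested direction reversed.

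Immediate early genes were positive in 15 of 17 (median 0.24, camera adjusted p = 0.0105, adjusted p = 0.889 with an estimated correlation), with the transcription factor genes Egr1 at 1.11 (SE 0.29), Ier2 at 0.58 (SE 0.23) and, against the others, Egr2 at −0.37 (SE 0.15). This list lost its call without Tg mouse 2 (0.273) or WT mouse 1 (0.163). Ribosomal protein genes were positive in 36 of 38 (median 0.19, camera adjusted p = 0.00639, adjusted p = 0.889 with an estimated correlation), among them Rpl5 (1.06, SE 0.30), Rps16 (0.50, SE 0.33) and Rpl27 (0.32, SE 0.21), all parts of the ribosome. The ribosomal list reversed to −0.0294 without Tg mouse 3 and lost its call without WT mouse 1 (0.114) or WT mouse 3 (0.124). All 13 mitochondrially encoded genes were negative (median −1.45, camera adjusted p = 0.0102, adjusted p = 0.889 with an estimated correlation), with mt-Atp8 at −2.15 (SE 0.95), mt-Nd6 at −1.57 (SE 0.83) and mt-Nd4l at −1.60 (SE 0.88), the latter 2 of complex I. Their estimated correlation was 0.974, and their share of counts gave an exact permutation p = 0.6 (two-sided). Without WT mouse 1 they stood at 0.147, and without Tg mouse 2 (−1.13) they were not called. Nuclear oxidative phosphorylation genes were negative in 49 of 68 (median −0.07, camera adjusted p = 0.0374, adjusted p = 0.913 with an estimated correlation), such as the complex III gene Uqcrc1 (−0.37, SE 0.16), the complex IV gene Cox5a (−0.37, SE 0.19) and the ATP synthase gene Atp5k (−0.50, SE 0.25). They reversed to 0.0400 without Tg mouse 2 and lost their call without Tg mouse 1 (−0.0417), WT mouse 1 (−0.0203) or WT mouse 2 (−0.0743) and with library size only (−0.0566). Proteasome genes were negative in 26 of 31 (median −0.12, camera adjusted p = 0.0231, adjusted p = 0.889 with an estimated correlation), with the proteasome subunit genes Psmc4 at −0.39 (SE 0.14), Psmd13 at −0.21 (SE 0.14) and Psma4 at −0.19 (SE 0.13), and they lost their call without Tg mouse 1 (−0.103), Tg mouse 2 (−0.146) or WT mouse 2 (−0.0501), with library size only (−0.159) and with the letter as covariate (−0.0675).

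The heat shock and BAG3 chaperone network had 10 positive and 13 negative values of 23 in fibroblasts (median −0.05, camera adjusted p = 0.695). Autophagy and lysosome genes were negative in 17 of 23 (median −0.08, camera adjusted p = 0.0642). Extracellular matrix genes were positive in 16 of 24 (median 0.14, camera adjusted p = 0.653), but with library size only lay at 0.28 against 0.36 for all genes, and myofibroblast activation genes had a median of −0.08 and a mean of 0.01 (adjusted p = 0.890). Cardiomyocyte markers were negative in 12 of 13 (median −0.40, camera adjusted p = 0.127). Stress and fetal genes (median −0.30, adjusted p = 0.362), sarcomere genes (−0.09, adjusted p = 0.149) and calcium handling genes (−0.07, camera upward, above all genes at 0.43 with library size only, adjusted p = 0.861) were not called. Oxidative stress defence (−0.24, adjusted p = 0.0506), glycolysis (−0.16, adjusted p = 0.0651) and fatty acid oxidation genes (−0.06, adjusted p = 0.729) were not called. The unfolded protein response (−0.05, adjusted p = 0.812), interferon response (−0.08, adjusted p = 0.159) and cytokine genes (0.08, adjusted p = 0.434) gave no call. Neither did p53 and apoptosis (median 0.08, mean −0.02, camera downward, adjusted p = 0.812) or mitochondrial dynamics genes (0.07, adjusted p = 0.923). Clock genes (0.03, adjusted p = 0.358), smooth muscle markers (0.15, but 0.34 against 0.36 for all genes with library size only, adjusted p = 0.451) and erythroid markers (−0.37, adjusted p = 0.149) were not called.

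Under the same limits, the single genes with the smallest p values in fibroblasts did not pass. Saa3, an acute phase serum amyloid gene, stood at 3.19 ± 1.00 CPM in Tg+ and 16.5 ± 4.06 CPM in Bag3-WT mice (log2FC −2.36, SE 0.30, adjusted p = 0.768). The myeloid receptor gene Cd300d (−0.87, SE 0.16, 8.53 against 15.6 CPM) and the G protein regulator gene Rgs10 (−0.63, SE 0.15, 26.9 against 41.5 CPM) were also lower. Higher were Egr1 (1162 ± 326 against 540 ± 69.9 CPM), the intermediate filament gene Synm (0.60, SE 0.15, 19.6 against 12.9 CPM) and the DNA-binding gene Ahdc1 (0.59, SE 0.15, 35.1 against 23.2 CPM).

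Of 13571 genes, edgeR called 0 between genotypes in fibroblasts, with 690 under an unadjusted 0.05 (324 higher, 366 lower) against 679 expected by chance. DESeq2 called 5 (Cd5l, Marco, Nanp, Nlrp1b and Saa3) and limma voom 0. Non-overlapping values of the 3 and 3 mice were found for 1777 genes, 13.1%, where 10% arises by chance. The self-test found 47 of 66 planted 4-fold and 8 of 67 planted 2-fold changes. Camera called 12 of 31 lists (4 higher, 8 lower), and 0 with an estimated correlation or with fry (all adjusted p ≥ 0.671).

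The last comparison asked whether the genotype difference itself differed between the cell types. The helicase gene Dhx35 in cardiomyocytes was at 6.42 ± 1.40 CPM in Tg+ and 0.115 ± 0.119 CPM in Bag3-WT mice, against 3.15 and 3.29 CPM in fibroblasts (difference of log2FC 5.80, SE 1.13, adjusted p = 1, n = 3 per group). Its cardiomyocyte counts were 123, 96 and 55 in Tg+ and 0, 2 and 1 in Bag3-WT mice. The log2FC therefore rests on 3 counts in all on the Bag3-WT side. None of the genes named for this comparison passed (adjusted p = 1 each). The lipase inhibitor gene Angptl4 (2.01, SE 0.54) and the innate immune kinase gene Tbk1 (1.48, SE 0.40) were higher in Tg+ cardiomyocytes relative to fibroblasts. Zbed6, a transposon-derived repressor gene (−1.71, SE 0.45), the ubiquitin ligase gene Cul7 (8.29 against 17.9 CPM in cardiomyocytes, 11.7 against 8.09 CPM in fibroblasts) and the heart muscle kinase gene Alpk3 (−1.73, SE 0.50, 6.33 against 13.7 CPM in cardiomyocytes) were lower. Bag3 was at −0.14 (SE 0.73, adjusted p = 1), and Bag3 by genotype by cell type reversed to 0.563 without WT mouse 1 and 0.345 without Tg mouse 2. Macrophage markers, all 13 with positive values, were not called (median 0.26, camera adjusted p = 0.0692).

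Of 13891 genes, edgeR called 0 for this difference, with 124 under an unadjusted 0.05 (68 higher, 56 lower) against 695 expected by chance, and DESeq2 and limma voom called 0. Genotype log2FC values of the cell types correlated across 12162 genes at r = 0.226 (genes are not independent), and 5 genes were under an unadjusted 0.05 in both, where 4.49 were expected. Camera called 9 of 31 lists for this difference and 0 with an estimated correlation.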

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

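The chance splits were chosen before the result was seen, and the tests on the lower muscle gene lists in Tg+ cardiomyocytes only after it was seen. What singled out the results of the next paragraph was a call by camera on the difference of the genotype effect between cell types, fixed beforehand.

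The genotype difference itself differed between cardiomyocytes and fibroblasts for 9 of 31 lists under the preset correlation. It was lower in cardiomyocytes for calcium handling and ion channels (median difference of log2FC −0.582, camera adjusted p = 0.00201, adjusted p = 0.726 with an estimated correlation), sarcomere and Z-disc genes (−0.400, adjusted p = 0.00764, adjusted p = 0.830 with an estimated correlation, as for all lists that follow) and cardiomyocyte markers (−0.260, adjusted p = 0.0256). The same held for inflammatory cytokines (−0.520, adjusted p = 0.0350), the interferon response (−0.441, adjusted p = 0.0346) and fibroblast markers (−0.404, adjusted p = 0.0346). Fatty acid oxidation (−0.175, adjusted p = 0.0398) and nuclear oxidative phosphorylation (−0.164, adjusted p = 0.0346) also lay lower, and the proteasome higher (0.239, adjusted p = 0.0346). With fry the adjusted p was 0.877 for all 9. Under library size only the median of all genes moved by 0.30, so these medians are read relative to the other genes.

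Chance cannot be judged from 10 splits of 6 mice, since 10 splits are too few to pass 5%. A real count of 0 genes is reached by every split, so the gene counts of the genotype comparisons were fixed in advance and tell nothing. In cardiomyocytes 10 of 10 splits gave as many genes as the real count of 0 (highest other 1). There 2 of 10 splits gave as many lists as the real 15 (highest other 15). Genes under an unadjusted 0.05 numbered 89 in the real split, and 2021 with Tg mouse 1, Tg mouse 2 and WT mouse 2 against the other mice. In fibroblasts 10 of 10 splits reached the real 0 genes (highest other 3) and 7 of 10 splits the real 12 lists (highest other 14). For the difference between cell types 10 of 10 splits reached 0 genes (highest other 2) and 5 of 10 splits the real 9 lists (highest other 17). For cell type, 1 of 32 exchanges within mice, the real one, reached 6190 genes (highest other 0), which argues against chance.

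Lower muscle, sarcomere and respiratory chain lists in Tg+ cardiomyocytes were weighed against 3 technical explanations. A lower share of cardiomyocytes in the Tg+ preparations remains open, since the endothelial minus macrophage score differed by 0.786 (SE 0.437, n = 3), under 2 standard errors. This fails to exclude it and is no evidence for it. Such a share would raise the other cell types together. Scores differed by 0.210 (SE 0.483) for endothelial and 0.00397 (SE 0.447) for smooth muscle markers. They differed by −0.117 (SE 0.326) for fibroblast, −0.576 (SE 0.603) for macrophage, −0.669 (SE 0.747) for lymphocyte and −1.41 (SE 1.72) for mesothelial markers. Tg mouse 1 alone, whose libraries also hold airway transcripts, may account for part, since cardiomyocyte markers by genotype in cardiomyocytes moved from −0.641 to −0.383 without it and the nuclear respiratory list lost its call (−0.179). Dilution by skin and limb transcripts, highest in Tg mouse 3 and WT mouse 3, was weighed by leaving out both mice. Without both mice the markers (−0.827), the sarcomere list (−0.832) and the mitochondrial (−1.60) and nuclear respiratory lists (−0.325) were all still called under the preset correlation. Tg mouse 1, with the lowest marker score (5.77 against 6.66 in Tg mouse 2), weighs more in that fit, so the larger values rest more on it. The skin and limb list then had medians of 9.24 and 12.3 CPM in Tg+ against 30.1 and 11.8 CPM in Bag3-WT columns, where dilution needs more in Tg+. Such material thus stayed in the fit, highest in WT mouse 1. The medians speak only to dilution by skin and limb transcripts, of which they give no sign. Airway transcripts of Tg mouse 1 were not part of this check, so dilution by them remains open. Whether skin and limb material brought muscle transcripts of its own was not tested. A change within Tg+ cardiomyocytes was not tested, and genotype stays open as a cause.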

How the results depend on the processing

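All tests here were chosen before the result was seen, except the fits without mitochondrial genes, with deposited factors, and without Tg mouse 3 and WT mouse 3. The limits below are given as measured, and the cause was not tested.

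Genotype in cardiomyocytes gave 0 genes, but library size only gave 2 (Dhx35 and Wif1), the DESeq2 Wald test 3 (Dhx35, Stard9 and Wif1), and the replicate block with libraries counted as independent 2 (Dhx35 and Ttn). The replicate block with the mouse as random effect gave 0, and there Cd79b by genotype in cardiomyocytes reversed to 0.220. Genotype in fibroblasts gave 2 genes with library size only (Bsx and Nanp) and 5 with the DESeq2 Wald test. Genotype by cell type gave 1 with library size only (Dhx35). Nanp had 15, 14 and 15 counts in Tg+ and 0 in each Bag3-WT fibroblast library, Wif1 25, 584 and 612 against 16, 9 and 16 in cardiomyocytes, Bsx 20, 10 and 240 against 18, 11 and 5 in fibroblasts. Cell type gave 457 genes higher and 6616 lower in cardiomyocytes with library size only, and 6557 in all with no replicate block. Camera calls fell to 0 with the estimated correlation and 0 with fry in cardiomyocytes, and to 0 and 0 in fibroblasts. Other settings called 11 to 14 lists in cardiomyocytes, 9 to 14 of them among the main 15, and 8 to 16 in fibroblasts, 5 to 11 of them among the main 12, with 0 of the main lists called in the opposite direction.

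Values of named genes and lists that changed sign are given as the lowest and highest fit without 1 mouse. Bag3 by genotype in cardiomyocytes ran from −0.551 (without WT mouse 3) to 0.447 (WT mouse 1). Bag3 by genotype in fibroblasts ran from −0.201 (Tg mouse 2) to 0.428 (Tg mouse 3), and was −0.146 with the other cell type markers as covariate. Bag3 by genotype by cell type ran from −0.662 (Tg mouse 3) to 0.563 (WT mouse 1). For the following genes and lists in cardiomyocytes the highest value was without Tg mouse 3. Muc16 by genotype in cardiomyocytes ran from −1.25 to 0.0131, Upk3b by genotype in cardiomyocytes from −1.16 to 0.166 (0.0864 with library size only), and mesothelial markers by genotype in cardiomyocytes from −1.14 to 0.193, each lowest without Tg mouse 1. H2-DMb1 by genotype in cardiomyocytes ran from −0.837 (Tg mouse 1) to 0.0336, and H2-DMa by genotype in cardiomyocytes from −0.701 (Tg mouse 2) to 0.104. Inflammatory cytokines by genotype in cardiomyocytes ran from −0.693 to 0.117 and MHC class II by genotype in cardiomyocytes from −0.639 to 0.223, both lowest without Tg mouse 2. MHC class II stood at 0.150 without Tg mouse 3 and WT mouse 3, where the macrophage (−0.0533), lymphocyte (−0.261), mesothelial (−0.0998), extracellular matrix (−0.477) and cytokine lists (−0.141) lost their calls. Lymphocyte markers by genotype in cardiomyocytes ran from −0.811 (without Tg mouse 1) to 0.118 (WT mouse 2), where the call was lost and the tested direction stayed.

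In fibroblasts, mt-Nd4l by genotype in fibroblasts ran from −2.07 (without WT mouse 2) to 0.0571 (WT mouse 1), and mitochondrially encoded oxidative phosphorylation from −1.91 to 0.147 without the same mice. Fibroblast markers by genotype in fibroblasts ran from 0.0328 (WT mouse 1, where the tested direction reversed) to 0.807 (WT mouse 2). Nuclear oxidative phosphorylation ran from −0.261 (Tg mouse 3) to 0.0400 (Tg mouse 2), and cytosolic ribosomal proteins from −0.0294 (Tg mouse 3) to 0.310 (Tg mouse 2). Without Tg mouse 3 and WT mouse 3, the ribosomal list stood at −0.0817 and Rps16 by genotype in fibroblasts at −0.00412, and the lymphocyte (−0.342) and MHC class II lists (−0.191) lost their calls. Lymphocyte markers by genotype in fibroblasts ran from −1.07 (without Tg mouse 1) to 0.236 (WT mouse 1).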

Other observations

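All tests in this part were chosen only after the result was seen, and the genes were singled out from their values. Levels are CPM of nuclear counts.

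Of 12 transcription factor genes of skin and limb mesenchyme, 7 were higher in each cardiomyocyte column than in each fibroblast column. The list had a median of gene means of 32.0 CPM over cardiomyocyte and 0.469 CPM over fibroblast columns. By the list median, cardiomyocyte columns fell into a high and a low group. Not every member followed these groups, with Tfap2a at 2.65 CPM in WT mouse 1 and 72.2 CPM in Tg mouse 2. The list medians were 35.8 CPM in Tg mouse 3, 32.0 in WT mouse 3 and 30.1 in WT mouse 1. They were 12.3 CPM in Tg mouse 2, 11.8 in WT mouse 2 and 9.24 in Tg mouse 1. The columns overlapped for Msx1 (20.4 to 39.2 against 17.2 to 47.7 CPM), Hoxa5 (4.32 to 24.8 against 7.97 to 26.9 CPM), Tbx4 (at most 1.15 against at most 0.822 CPM), Tfap2a and Tbx5, which is also a heart gene. The trunk and limb skin gene En1 ran from 2.36 to 146 CPM against at most 0.442 CPM in fibroblasts. The dermal gene Twist2 ran from 19.7 to 282 against 2.02 to 5.92 CPM, and the limb bud gene Prrx1 from 59.8 to 152 against 6.83 to 17.2 CPM. The limb and dermis gene Tbx15 (4.49 to 197 against at most 0.632 CPM) and the trunk patterning gene Hoxc8 (8.25 to 86.7 against at most 0.540 CPM) had the same pattern. Col1a1, Acta2 and the cell cycle gene Cenpf were also higher in cardiomyocyte than in fibroblast libraries, as described in the report. In CPM TMM-scaled over all 12 columns, Acta2 and Col1a1 did not follow the high and low groups. Acta2 was lowest in WT mouse 1 (51.4), and Col1a1 was lower in Tg mouse 3 (1306) than in Tg mouse 1 (1537). Cenpf followed them, with 4.75 in WT mouse 1 above 3.91 in WT mouse 2. No explanation of this pattern was tested.

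Among myeloid genes in fibroblasts, the macrophage survival factor gene Cd5l had 26, 11 and 6 counts in Tg+ and 138, 89 and 47 in Bag3-WT mice. The scavenger receptor gene Marco had 11, 10 and 5 against 84, 76 and 23 counts. The inflammasome gene Nlrp1b had 28, 32 and 21 against 109, 70 and 95 counts, and Saa3 113, 70 and 47 against 520, 303 and 359. These genes were called by DESeq2 only, which made 37 false calls among 117 in the simulated fibroblast data.

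Y-linked genes in the cardiomyocyte libraries of Tg mouse 3, with letter F, were weighed against 3 explanations. RNA of male mouse heart cells is an unlikely source of the Eif2s3y counts, since Ddx3y, Kdm5d and Uty together stood at 0.366 per Eif2s3y count (upper 95% limit 0.469) against at least 1.21 in libraries with letter M. They had 62, 1 and 0 counts where Eif2s3y predicts at least 163, 14.5 and 30.8. It may be a source of Ddx3y and remains open there, since the value of 0.0161 Kdm5d and Uty counts per Ddx3y count (at least 0.113 with letter M) rests on 1 count. For Usp9y it also remains open, with 1.55 per Ddx3y count against at most 0.5 in cardiomyocytes and 0.00308 in fibroblasts with letter M. The 0.5 is that of WT mouse 3, with 90 Usp9y counts in cardiomyocytes and 0 in fibroblasts. Cardiomyocyte libraries with letter M may thus hold the same unexplained counts and are no clean reference. Reads of the X-linked copies are unlikely, since Usp9y stood at 111 per 1e3 Usp9x counts against 0 in fibroblasts of this mouse (1.25 with 3 counts). RNA that differs in sequence from mouse, read through short shared stretches, may be a source and remains open. Of 65 single-exon copies under 1 CPM in every fibroblast column, 3.08% were high in cardiomyocytes (95% interval 0.375 to 10.7). Under the same limit it was 3.66% of 273 other single-exon genes (Fisher's exact p = 1, two-sided). Only 2 copies were high, Csl and Exosc6, and Exosc6 shared 100% of its stretches with Aars, so the comparison is weak. A sample exchange was not tested.

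Airway transcripts in the cardiomyocyte libraries of Tg mouse 1 were also weighed. The secretory list of 10 genes had a median of 239 CPM there and at most 0.708 CPM in other cardiomyocyte columns, with the airway defence gene Bpifa1 at 2576 in rep1 and 2592 in rep2, the club cell genes Scgb1a1 at 564 and Scgb3a2 at 246, and Cyp2f2 at 262. Lung tissue may contribute and remains open, since the alveolar surfactant gene Sftpc was lowest there (0.898 CPM against 4.48 to 27.8 CPM in the others), while Sftpd (5.65 CPM) and Sftpa1 (4.23 CPM) were highest there. Airway lining cells may be the source, since the ciliated and basal list had a median of 5.97 CPM against at most 0.636 CPM. Foxj1, Ccdc153, Tppp3, Krt5 and Krt15 were highest there among cardiomyocyte columns. Krt14 (5.65 against 13.8 CPM in WT mouse 2), Dynlrb2 (1.54 against 2.23 CPM in WT mouse 3) and Trp63 (1.80 against 2.36 CPM in WT mouse 2) were not. Reads from another library of the series are unlikely, since the highest Bpifa1 elsewhere was 23.2 CPM (fibroblasts of Tg mouse 1), and libraries of other studies remain open.

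Alveolar markers (7) had medians of at most 1.97 CPM, thyroid markers (3 found of 4) of at most 0.636 CPM and testis germ cell markers (6 found of 11) a highest value of 0.442 CPM in cardiomyocyte columns. The secretory gene Cbr2 was high in all columns (36.2 to 653 CPM).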
